A study of Mus musculus with 6 samples.

How the data were processed

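RNA of bone marrow was sequenced in 6 libraries, 3 labelled control and 3 labelled Che-1 silencing. Per the labels' protocols the RNA was total RNA made into stranded libraries after depletion of ribosomal RNA. Per the submitters' processing notes, TopHat, Cufflinks, Cuffdiff and HTSeq were used, with build mm9, and versions are not given in the sources used here. No coordinates were used.

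The authors deposited a table of raw counts of 92 ERCC spike-ins per library, with 5 HTSeq summary rows that name no spike-in, per the file headers. Those rows held between 0.0434% and 0.221% of each library's reads in that table and stayed out of the spike-in totals, but 2 of them entered the deposited size factors and so the spike-in scale. The authors also deposited a gene table of 17173 genes. Its means are gene counts divided by spike-in size factors and averaged over the 3 libraries of a group (unit: signal), beside the authors' ratio of the group means (fold), its log2 value, the authors' p-value and an adjusted p-value, per the file headers. Its columns have the layout of the DESeq package's negative binomial test. No value per library and gene was in the columns used here.

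Counts per library were therefore solved for. Size factors were the median ratio over the rows of the spike-in table without a 0, which included 2 summary rows beside 70 spike-ins (72 rows). With these factors every group mean above 0 and below 50 (4739 control, 3330 Che-1 silencing) matched exactly 1 set of 3 whole counts, and with factors from spike-ins only 0 did. The tolerance was a relative 1e-15 plus 0.55 of the last printed digit. In 2000 simulated means per group 1999 came back with 1 solution, all correct, and means moved off the grid gave none. In this way 17076 genes, or 99.4%, were recovered. The remaining 97 genes, whose means over both groups were all 10713 or more, were left out of the fits. They held 18.3% of the summed control means and 17.3% of the summed Che-1 silencing means. Xist is among them. The deposited scale was kept as the spike-in scale.

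The planned tests assumed values per library. Since the table held group means of normalized counts, limma on log2(normalized count + 1) was the main test, as fixed for normalized counts, and edgeR and DESeq2 on the recovered counts were alternatives. limma (version 3.58.1, R 4.3.3) was run with a group term and a mean trend (eBayes), on 14604 genes with a mean of at least 10 over the 6 libraries. In the spike-in fit the prior degrees of freedom were infinite, so its SEs and p-values rest on a spread shared by genes of like level. In the relative fit they were 2.42. Benjamini-Hochberg adjustment was over all genes tested, with a threshold of 0.05. Log2 differences are on the log2(value + 1) scale and understate the change of low genes. On the relative scale each library's median log2 level was set equal. Lists were tested with camera (preset correlation 0.01, and an estimated correlation beside it) on the relative scale. They were also tested with fry on the spike-in scale and, beside it, on the relative scale. fry asks whether a list's genes move on balance in a single direction and does not compare the list with other genes. Of 33 lists fixed before the data were examined, with 1128 distinct genes, 32 had tested members. The list of mitochondrial genome genes had 0 genes in the table used here, and 84 list entries had no row in it. Single values per library were compared by an exact two-sided permutation test, which cannot go below 0.10 with 3 against 3 libraries. Floors of 3 reads cover counting error only. A single read is a large share of a gene near the minimum mean, so depth limits the precision of such genes most. The protocols say that libraries were made in triplicate and do not name separate animals, so p-values may not measure the spread between mice.

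The genes named were fixed by rule before the data were examined: Aatf; up to 12 rises and 12 falls on the spike-in scale and up to 8 and 8 on the relative scale, by size, among genes past the threshold, at or above the median level (621 normalized counts), without overlap between groups and with an ordinary symbol; and in each list up to 4 members with the lowest p on each scale. Where none passed in a direction, the 6 with the lowest p were named as values. Some genes that the rule takes in are not reported here.

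On simulated counts with the real means, library sizes and dispersions and 200 changed genes, limma on the relative scale found 22.0% of 2-fold and 99.0% of 8-fold changes among 14425 genes and called 11 unchanged genes. With the spread of control libraries 2 and 3 alone it found 100% of both among 14464 genes. In 100 simulated data sets of 14604 genes without a group effect, with library levels spread as within the real groups (SD 0.52 log2 units), 1 gave more than 1000 calls on the spike-in scale, with 5901 calls.

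Alternatives were the pseudocount (0.1, 5), the minimum mean (none, 50), each library left out in turn, the replicate number as a block, other settings of limma, edgeR 4.0.16, DESeq2 1.42.0, other thresholds and other scales between libraries. Chosen after seeing the data were sums of the libraries that resembled each other, limma without moderation, and a relative scale without a trend with transcript length. Symbols, chromosomes and transcript lengths for that trend and for X- and Y-linked genes came from GENCODE M21 (build GRCm38), in which 99.2% of the tested genes had a length. Reads of near-identical gene copies or of overlapping genes may be split or dropped by the counting, whose settings are not given in the sources used here. Recovery and figures used Python 3.11.15.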

Results

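Bone marrow of a mouse model of multiple myeloma, a cancer of antibody-secreting plasma cells, was profiled by RNA sequencing in 6 libraries, 3 labelled control and 3 labelled Che-1 silencing. Che-1 is the protein encoded by Aatf, a nuclear factor that binds RNA polymerase II. Synthetic ERCC spike-in RNAs had been counted in every library, and the authors' gene table was scaled to them, so levels per spike-in (the spike-in scale) were compared as well as levels relative to the median gene of each library (the relative scale). Gene reads recovered per library numbered 11317166, 15930992 and 17809057 for control replicates 1, 2 and 3, and 24899535, 21241846 and 14373200 for Che-1 silencing replicates 1, 2 and 3. Spike-in reads numbered 471796, 1149392 and 1105881 in the control libraries and 445186, 228087 and 414769 in the libraries labelled Che-1 silencing. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries, which may be technical in part. In the limma fit on the spike-in scale that spread is shared by genes of like level and is not each gene's own. Control libraries 2 and 3 lay closest to each other (mean chi-square per gene 2.12, median 0.63 where sampling noise alone gives 0.455). Their spike-ins, which carry no biology, also exceeded it (mean chi-square 1.54, median 1.003), so these values do not show whether control libraries 2 and 3 came from separate samples. They were entered as 2 replicates, and the counts and the Aatf call on the spike-in scale are also given with both summed into 1. Control replicate 1 differed from control replicates 2 and 3 more in its genes (mean chi-square 49.6 and 52.6) than in its spike-ins (4.66 and 5.28). For control replicate 1, that argues against technical spread alone from the addition of the spike-ins onward.

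The targeted gene itself was not lower in the libraries labelled Che-1 silencing. Aatf stood at 896, 396 and 421 normalized counts in control replicates 1, 2 and 3 and at 1986, 3808 and 1223 in the libraries labelled Che-1 silencing, a mean of 571 ± 282 (SD, n = 3) against 2339 ± 1328 (SD, n = 3). On the spike-in scale Aatf was 1.98 log2 units higher in the libraries labelled Che-1 silencing (SE 0.57, limma adjusted p = 0.0021), with all 3 above all 3 control libraries. Relative to the median gene the difference was 0.45 log2 units in the same direction (SE 0.19), which did not pass (limma adjusted p = 0.143). The direction goes against the label, so every direction below is that of the libraries labelled Che-1 silencing and not of a measured loss of Aatf. The groups also differed in Y-linked reads and in Xist, so no difference between them can be told apart from one of sex. The genotype label says Che-1 silencing, while the sample titles call these libraries vkche and the others Control. The titles do not mention silencing and do not say what vkche stands for. The call on the spike-in scale ended without control replicate 2 (limma adjusted p = 0.0568) and without control replicate 3 (limma adjusted p = 0.0576). It also ended with control libraries 2 and 3 summed into 1 (limma adjusted p = 0.0567), in a range over all alternatives from 2.2e-136 to 0.158.

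Most transcripts were more abundant per spike-in RNA in the libraries labelled Che-1 silencing. The title of the series asks about global transcription. A spike-in scale gives RNA levels per amount of spike-in added, and whether that amount was set per cell is not stated here. It therefore measures neither RNA per cell with certainty nor transcription itself. The median over 14604 tested genes of the log2 difference was 1.54, and 93.9% of the genes had a higher mean log2 level in the libraries labelled Che-1 silencing. The level of the median gene was 8.60, 7.89 and 8.05 log2 units in control replicates 1, 2 and 3, with a mean of 8.18 ± 0.37 (SD, n = 3), and 9.65, 10.38 and 9.10 in the libraries labelled Che-1 silencing, with a mean of 9.71 ± 0.64 (SD, n = 3). All 3 lay above all 3 control libraries (exact two-sided permutation p = 0.10, the smallest that 3 against 3 libraries allow). Spike-in reads came to 5.86 ± 1.55 (SD, n = 3) per 100 recovered gene reads in the control libraries and to 1.92 ± 0.913 (SD, n = 3) in the libraries labelled Che-1 silencing (exact two-sided permutation p = 0.10). The spike-in totals themselves differed by -1.28 log2 units (exact two-sided permutation p = 0.10), and the shift of the median gene rests on them. Single spike-ins, compared after the data were seen, disagreed on its size: among 31 with at least 100 reads in every library the log2 difference in reads ran from -1.87 to -0.40 (SD 0.32). The proportions between spike-ins differed more across the groups (mean chi-square 27.3 to 210) than within the control libraries (1.54 to 5.28) or between Che-1 silencing replicates 1 and 2 (3.04). Che-1 silencing replicate 3 differed from replicates 1 and 2 as well (102 and 72.3). Deeper libraries give larger chi-squares, but depth alone does not order these values. Control replicates 2 and 3, with the most spike-in reads, had the lowest, 1.54.

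**Figure D1:**
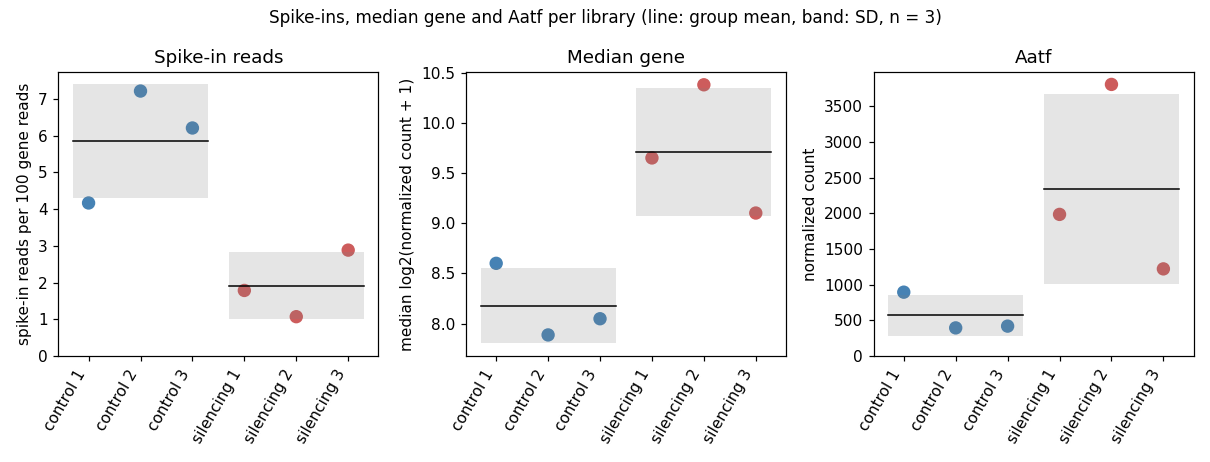
Each point is 1 library: spike-in reads per 100 recovered gene reads (left), the median gene's log2(normalized count + 1) (middle) and the normalized count of Aatf (right), with the mean as a line and the SD as a band (n = 3 per group). The libraries labelled Che-1 silencing had fewer spike-in reads per gene read, and Aatf lay between 1223 and 3808 there against 396 to 896 in the control libraries.

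Rgs13, Mef2b and Mybl1 were among the genes with large rises on the spike-in scale. Rgs13, a regulator of G protein signalling, rose from 25.8 ± 13.4 to 10401 ± 9126 normalized counts (SD, n = 3 each), or 6.84 log2 units (SE 0.53, limma adjusted p = 1.4e-34), and the transcription factors Mef2b and Mybl1 rose by 5.94 (SE 0.55) and 5.93 (SE 0.57). Nuggc, a GTPase of germinal centre B cells, rose by 5.75 log2 units (SE 0.55) and S1pr2, a sphingosine-1-phosphate receptor, by 5.13 (SE 0.56). Other genes named by the rule were Irak1bp1 (5.42), Pde1c, a phosphodiesterase (5.17), Rassf6 (5.07), Tex14 (5.01), Lipc, a lipase (4.84), and Havcr1, a T cell immunoglobulin and mucin receptor (4.74). These rises were uneven between the libraries: Rgs13 had 13650 and 17457 normalized counts in Che-1 silencing replicates 1 and 2 and 95.0 in replicate 3. The SEs and p-values on the spike-in scale do not reflect this, as they rest on a spread shared across genes. Relative to the median gene Rgs13 did not pass (limma adjusted p = 0.0963). Havcr1 was higher in each of these 3 libraries than in any control library, at 4085, 7013 and 999 normalized counts against 121, 92.1 and 132 in the control libraries.

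Falls were few. Of the genes above the median level, 2 met the rule for a fall on the spike-in scale. Podxl, a sialomucin of blood vessels and progenitor cells, fell from 1126 ± 215 to 297 ± 130 normalized counts (SD, n = 3 each; log2 difference -1.99, SE 0.55, limma adjusted p = 0.0015). Ddx3y, a Y-linked RNA helicase, had 2099 ± 390 (SD, n = 3) in the control libraries and 0 reads in each library labelled Che-1 silencing. With a floor of 3 reads per library it was at least 427-fold lower there.

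In all, 9745 of the 14604 genes tested rose and 109 fell on the spike-in scale (limma, adjusted p of at most 0.05), whereas 0 rose and 4 fell relative to the median gene. In 9927 genes all 3 libraries labelled Che-1 silencing lay above all 3 control libraries on the spike-in scale. In 64 genes all 3 lay below. Chance gives 10% per gene in both directions together, but a shift of whole libraries moves most genes at once. The share is therefore no test against chance. The calls rest on moderation across genes: limma with each gene's own 4 degrees of freedom gave 0 rises and 4 falls, against 10359 genes at an unadjusted p under 0.05 in the moderated fit and 10078 rises and 84 falls by edgeR. The rises numbered 3223 and 3536 without control replicate 2 or 3 and 5649 and 6042 without Che-1 silencing replicate 1 or 2, and the falls 53, 50, 25 and 37 in the same order, with 234 falls without Che-1 silencing replicate 3. With control libraries 2 and 3 summed into 1, an alternative chosen after the data were seen, 3451 genes rose and 55 fell, and with Che-1 silencing libraries 1 and 2 summed as well 528 rose and 28 fell.

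Relative to the median gene, the calls among the tested genes were 4 Y-linked genes. Ddx3y, Eif2s3y, Kdm5d and Uty had reads in all 3 control libraries and 0 in each library labelled Che-1 silencing, at least 427-, 245-, 215- and 190-fold lower with a floor of 3 reads per library (limma adjusted p = 1.8e-04 for each). Eif2s3y, Kdm5d and Uty fall outside the rule for named genes and were named after their values were seen. No tested gene rose by limma or by edgeR. The 97 genes without recovered counts were outside these fits. Among them, Xist had deposited means of 5.64 in the control libraries and 68685 in those labelled Che-1 silencing. The deposited means of 4933409K07Rik were 27810.5 and 0 in the same order. DESeq2 on the recovered counts called 2189 rises and 1777 falls, and 5128 genes had an unadjusted p under 0.05 by limma, 2596 of them higher. The groups did not overlap in 5872 genes, or 40.2%. Chance gives 10% per gene, but genes moved together, so the share is no test against chance. A split across the labels put control replicate 1 with Che-1 silencing replicates 1 and 2. It gave 4374 genes at an unadjusted p under 0.05 by limma. Among genes at or above the median level (621 normalized counts) that were higher relative to the median gene, the lowest p-values belonged to Vmn2r96 (log2 difference 1.52, SE 0.15), Tex14 (3.48, SE 0.37), Ctsh, a lysosomal protease (1.01, SE 0.11), Psma4, a proteasome subunit (1.08, SE 0.12), Erp44, a chaperone of the endoplasmic reticulum (1.35, SE 0.15), and BC064078 (1.74, SE 0.19), with limma adjusted p-values from 0.0559 to 0.0568. Below that level Ccl3 had a lower one (2.27, limma adjusted p = 0.0535). The counts rested on Che-1 silencing replicate 3, without which 4046 genes rose and 3666 fell. Without control replicate 1 the counts were 26 and 72.

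Gene lists for bone marrow and for the processes named in the title were fixed before the data were examined. All 32 lists with tested members were measured on both scales, and 14 were higher and 5 lower than the other genes on the relative scale (camera with a preset correlation of 0.01, adjusted p of at most 0.05). None of the 19 passed with an estimated correlation (lowest adjusted p = 0.725 with an estimated correlation). On the spike-in scale 1 list, the plasma cell genes, passed the self-contained fry test (adjusted p = 0.041). Several others, among them the respiratory chain and proteasome genes, lay just above the threshold (fry adjusted p = 0.0512). The shift of most genes enters that test, so it does not set the plasma cell genes apart. On the relative scale fry passed 0 lists (lowest adjusted p = 0.0655). Counts of members that rose or fell below are from limma on the spike-in scale, where the median gene rose by 1.54 log2 units. Of all 14604 genes tested 9745 rose there, so a majority of rises in a list is not particular to it.

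Energy metabolism and protein turnover stood above the other genes. All 59 nuclear respiratory chain genes rose on the spike-in scale, and their median lay 0.58 log2 units above the median gene (camera adjusted p = 5.7e-13, adjusted p = 0.725 with an estimated correlation). Cox6c, a subunit of cytochrome c oxidase, had 782 ± 264 normalized counts in the control libraries and 4565 ± 2108 in the libraries labelled Che-1 silencing (SD, n = 3 each). Cox6b1 had 921 ± 280 and 5431 ± 2758. All 34 proteasome genes rose too, with a median 0.70 above the median gene (camera adjusted p = 1.3e-12, adjusted p = 0.725 with an estimated correlation). The immunoproteasome subunits Psmb8 and Psmb9 rose by 2.66 and 2.69 log2 units (SE 0.59 and 0.58). Adjusted over the list alone, 38 respiratory chain genes and 29 proteasome genes were higher on the relative scale, against 0 of either over all genes tested. The medians of both lists were 0.33 and 0.42 above the control mean in Che-1 silencing replicate 3. Of the 32 endoplasmic reticulum stress genes 30 rose, with a median 0.33 above the median gene (camera adjusted p = 3.6e-04, adjusted p = 0.725 with an estimated correlation), and 12 were higher and 1 lower on the relative scale adjusted over the list alone. The disulfide isomerase Pdia6 rose by 2.62 log2 units (SE 0.59) and Herpud1, a factor of protein degradation at the endoplasmic reticulum, by 2.51 (SE 0.59). Among 29 low-oxygen genes 24 rose, with a median 0.58 above the median gene (camera adjusted p = 0.0048, adjusted p = 0.725 with an estimated correlation), with 12 higher and 2 lower on the relative scale adjusted over the list alone. Its median was 0.80 over Che-1 silencing replicates 1 and 2 and 0.20 in replicate 3, or 0.09 for replicate 3 against control replicates 2 and 3 alone. Bnip3, a mitochondrial factor of autophagy, rose by 3.45 log2 units (SE 0.54), and the glycolytic enzymes Tpi1 and Pgk1 rose by 3.25 and 3.07 (SE 0.59 each), while Vegfa, a growth factor of blood vessels, did not pass (0.55, SE 0.57).

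Cell division genes rose on the spike-in scale. All 38 mitosis genes rose, with a median 0.99 above the median gene (camera adjusted p = 2.7e-06, adjusted p = 0.725 with an estimated correlation). Ttk, a spindle checkpoint kinase, rose by 3.47 log2 units (SE 0.56) and Nek2, a centrosome kinase, by 3.55 (SE 0.57). Of 44 replication genes 42 rose, among them the replication factor Cdc45 (2.96, SE 0.56), with a median 0.88 above the median gene (camera adjusted p = 3.1e-05, adjusted p = 0.725 with an estimated correlation). The medians of the mitosis and replication lists were 1.44 and 1.23 above the control mean over Che-1 silencing replicates 1 and 2, and 0.17 and 0.01 in replicate 3. Control replicate 1 exceeded the other control libraries by 1.06 and 1.01, and against control replicates 2 and 3 alone replicate 3 lay at 0.55 and 0.36. All 42 measured histone genes rose, with a median 0.68 above the median gene (camera adjusted p = 3.7e-04, adjusted p = 0.727 with an estimated correlation). That median was 1.09 over Che-1 silencing replicates 1 and 2 and -0.13 in replicate 3, and the latter turned to 0.26 against control replicates 2 and 3 alone. Their near-identical copies can share reads, so single members such as Hist1h3g (2.82, SE 0.58) are uncertain. Of 30 DNA damage checkpoint genes 29 rose (camera adjusted p = 0.0117, adjusted p = 0.729 with an estimated correlation), among them Lig4, a DNA ligase (3.06, SE 0.54), and the checkpoint kinase Chek1 (2.78, SE 0.54). That list's call ended without Che-1 silencing replicate 2 (camera adjusted p = 0.0638) and with both pairs of like libraries summed (camera adjusted p = 0.162). Its median was 0.47 over Che-1 silencing replicates 1 and 2 and -0.10 in replicate 3, or 0.12 for replicate 3 against control replicates 2 and 3 alone. Adjusted over the list alone, 0 genes of the mitosis, replication, histone and DNA damage lists passed on the relative scale, as over all genes tested.

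Among genes of RNA and ribosome production, all 57 ribosomal protein genes rose (median 0.36 above the median gene, camera adjusted p = 3.1e-08), as did all 37 core splicing genes (0.50, camera adjusted p = 6.7e-06) and all 46 ribosome assembly genes (0.44, camera adjusted p = 3.1e-05). None of these 3 lists passed with an estimated correlation (adjusted p = 0.725 with an estimated correlation for each), and adjusted over the list alone 0 of their genes passed on the relative scale, as over all genes tested. Rpl29 rose from 4841 ± 1423 to 24063 ± 12718 normalized counts (SD, n = 3 each), and Snrpd1, a core protein of splicing particles, by 2.80 log2 units (SE 0.57). Of 52 RNA polymerase II subunits and general transcription factors 49 rose, with a median 0.44 above the median gene (camera adjusted p = 1.5e-05, adjusted p = 0.725 with an estimated correlation). The subunits Polr2g and Polr2j rose by 2.92 and 2.54 log2 units (SE 0.56 each). The splicing, ribosome assembly and polymerase medians were 0.78, 0.68 and 0.56 over Che-1 silencing replicates 1 and 2, but 0.10, -0.02 and 0.09 in replicate 3. Against control replicates 2 and 3 alone replicate 3 lay at 0.20, 0.17 and 0.20. The ribosomal protein median was 0.43 over replicates 1 and 2 and 0.21 in replicate 3. Of 29 MYC-bound metabolic genes 28 rose (camera adjusted p = 2.3e-04, adjusted p = 0.725 with an estimated correlation), 6 of them higher on the relative scale adjusted over the list alone. Their median was 0.80 over Che-1 silencing replicates 1 and 2 and 0.22 in replicate 3, or 0.41 against control replicates 2 and 3 alone. Ldha, lactate dehydrogenase, rose by 2.95 log2 units (SE 0.58) and Odc1, the polyamine enzyme ornithine decarboxylase, by 2.60 (SE 0.58).

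**Figure D2:**
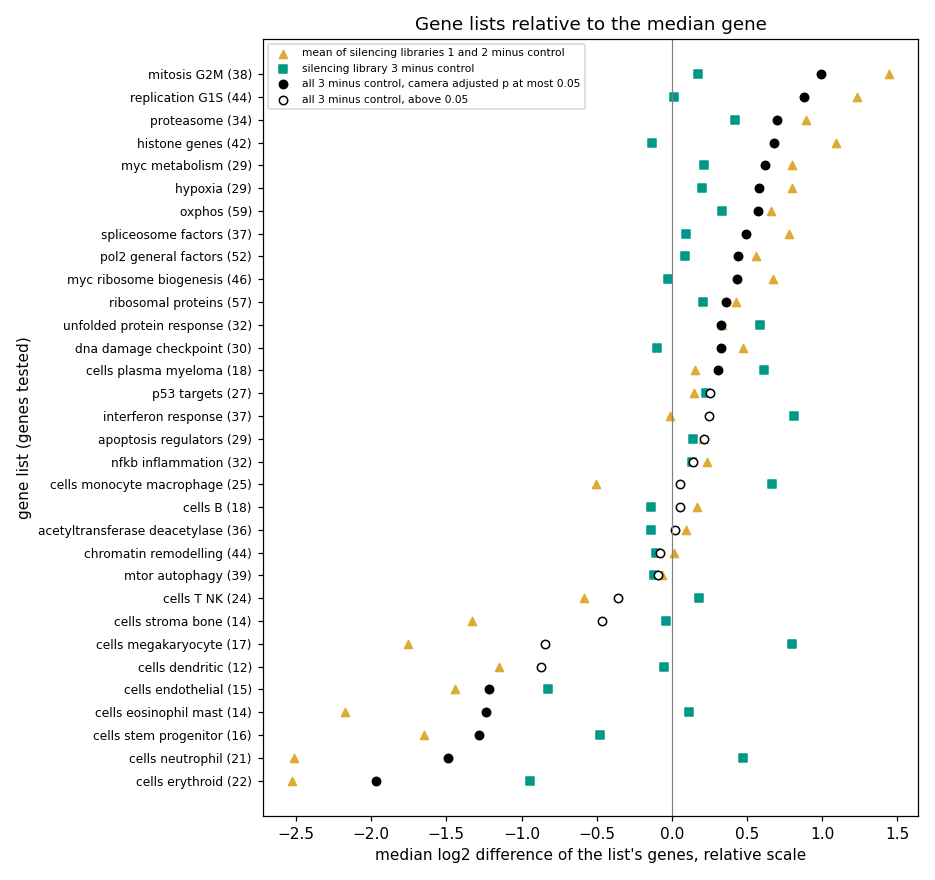
Median log2 difference from the control mean of each gene list's tested genes on the relative scale (x axis), with the number of genes in brackets; circles show all 3 libraries labelled Che-1 silencing, filled where camera's adjusted p with a preset correlation was at most 0.05, triangles the mean of replicates 1 and 2, and squares replicate 3. The neutrophil list lay at -2.52 for replicates 1 and 2 and at 0.47 for replicate 3, or at 0.08 for replicate 3 against control replicates 2 and 3 alone.

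Chromatin is a subject of the title of the series. Its lists of remodelling and histone-modifying genes did not pass, while the histone genes above did at the preset correlation. Of 44 nucleosome remodelling and histone methylation genes 33 rose on the spike-in scale, and their median relative difference was -0.08, with a mean of -0.0022, and 0.28 without a length trend (camera adjusted p = 0.879, and 0.0815 without that trend). Kdm6a, an X-linked histone demethylase, rose by 2.51 log2 units (SE 0.59), while the related Kdm6b did not pass (0.27, SE 0.57). The groups also differed in Xist and in Y-linked reads, so the rise of Kdm6a cannot be told apart from a difference in sex. Of 36 histone acetyltransferase and deacetylase genes 29 rose, with a median relative difference of 0.02 (camera adjusted p = 0.879). Hat1, a histone acetyltransferase, rose by 2.73 log2 units (SE 0.58) and Hdac4 did not pass (0.93, SE 0.56). Autophagy and mTOR genes had 30 rises among 39 members and a median relative difference of -0.09, or 0.10 without a length trend (camera adjusted p = 0.708), with Ddit4, an inhibitor of mTOR, rising by 2.47 log2 units (SE 0.56). The BCL2 family and death pathway genes (24 of 29 rose, camera adjusted p = 0.0672, against 0.0487 without control replicate 2 and 0.0266 without Che-1 silencing replicate 2) and the genes raised by p53 (22 of 27, camera adjusted p = 0.146) did not pass as lists. The death pathway list passed as higher without a filter on low values (camera adjusted p = 0.0126), with a pseudocount of 5 (0.0438), with control libraries 2 and 3 summed (0.0473) and with both pairs summed (0.0283). Bid, a pro-death BCL2 family member, rose by 2.99 log2 units (SE 0.57) and Cdkn1a, the cell cycle inhibitor p21, by 2.91 (SE 0.53).

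Most inflammatory genes rose on the spike-in scale, as did most genes tested (9745 of 14604). Of 37 interferon-stimulated genes 30 rose (camera adjusted p = 0.145), among them the chemokine Cxcl10 (3.09, SE 0.53) and the GTPase Gbp2 (2.98, SE 0.58). Their median relative difference was 0.81 in Che-1 silencing replicate 3 (0.68 against control replicates 2 and 3 alone) and -0.01 over replicates 1 and 2. The list passed as higher without control replicate 2 or 3 (camera adjusted p = 0.0383 and 0.0252) and without Che-1 silencing replicate 1 or 2 (camera adjusted p = 0.0041 and 0.0294). It passed also without a filter on low values (camera adjusted p = 0.0375), with control libraries 2 and 3 summed (0.0311) and with both pairs of like libraries summed (6.7e-04). Of 32 NF-kB and inflammatory genes 24 rose (camera adjusted p = 0.178). Ccl3, a chemokine of macrophages, rose from 23.1 ± 7.59 to 344 ± 145 normalized counts (SD, n = 3 each), Ccl4 rose by 3.21 log2 units (SE 0.58) and Tnf by 2.85 (SE 0.53).

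The plasma cell list had 14 rises among 18 tested genes (camera adjusted p = 0.0472, adjusted p = 0.725 with an estimated correlation), and its call ended without Che-1 silencing replicate 3 (camera adjusted p = 0.621) and without control replicate 1 (camera adjusted p = 0.231). It ended also on the relative scale without a length trend (camera adjusted p = 0.0757), with camera on the spike-in scale (0.143), with a minimum mean of 50 (0.0557) and with a pseudocount of 0.1 (0.0513). Its median was 0.15 over Che-1 silencing replicates 1 and 2 and 0.62 in replicate 3, or 0.53 for replicate 3 against control replicates 2 and 3 alone. Control replicate 1 differed from the other control libraries by -0.60. Adjusted over the list alone 5 of its genes were higher on the relative scale, against 0 over all genes tested. Mzb1, a chaperone of antibody assembly, rose from 823 ± 69.5 to 4239 ± 1380 normalized counts (SD, n = 3 each), and Ell2, an elongation factor of plasma cells, rose by 2.61 log2 units (SE 0.59). B cell genes had 12 rises among 18 and a median relative difference of 0.05, with a mean of -0.12 and camera's direction down (camera adjusted p = 0.879). Vpreb3, a gene of B cell precursors, rose by 3.19 log2 units (SE 0.53), while Rag1, the recombinase of antibody genes, did not pass (-1.08, SE 0.77) and Fcer2a, the B cell receptor for immunoglobulin E, did not pass (-0.10, SE 0.58). Of 25 monocyte and macrophage genes 16 rose and 1 fell (camera adjusted p = 0.43, against 0.0156 with both pairs of like libraries summed), with a median of 0.06, a mean of -0.12 and camera's direction up. Their median was -0.50 over Che-1 silencing replicates 1 and 2 and 0.66 in replicate 3 (0.45 against control replicates 2 and 3 alone), and camera's direction turned down without replicate 3 (camera adjusted p = 0.339). The complement genes C1qa, C1qb and C1qc rose by 3.06, 2.56 and 2.74 log2 units (SE 0.59 each). Some abundant genes of B cells and macrophages had no recovered counts and were outside these tests. Looked up after the data were seen, the ratio of deposited means was 12.9 for Ms4a1 and 11.9 for Lyz2, but 2.48 for Cd74. The authors' median fold was 2.95.

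Red cell precursor genes lay far below the median gene. None of 22 passed on the spike-in scale, and all 22 lay below the median gene, by a median of -1.97 log2 units (camera adjusted p = 4.1e-07, adjusted p = 0.725 with an estimated correlation), 21 of them lower on the relative scale adjusted over the list alone. Alas2, the heme synthesis enzyme of red cells, had 4959 ± 3972 normalized counts in the control libraries and 2835 ± 1752 in the libraries labelled Che-1 silencing (SD, n = 3 each). The median was -2.52 over Che-1 silencing replicates 1 and 2 and -0.94 in replicate 3, and -0.41 for replicate 3 against control replicates 2 and 3 alone. Control replicate 1 exceeded the other control libraries by a median of 1.64 log2 units in this list. Endothelial genes lay at a median of -1.22 relative to the median gene, at -1.44 over Che-1 silencing replicates 1 and 2 and at -0.82 in replicate 3, with 1 rise and 1 fall on the spike-in scale (15 of 15 lower on the relative scale, 11 adjusted over the list alone, camera adjusted p = 1.8e-05, adjusted p = 0.725 with an estimated correlation). Emcn, an endothelial sialoglycoprotein, fell by 2.35 log2 units on the spike-in scale (SE 0.54), yet it had 33.9 normalized counts in control replicate 1 and 793 and 926 in the other control libraries. Its call ended without control replicate 2 or 3 (limma adjusted p = 0.0662 and 0.0834) and without Che-1 silencing replicate 1 or 2 (limma adjusted p = 0.113 and 0.0635). Neutrophil genes (21 tested, median -1.49, camera adjusted p = 0.0014, adjusted p = 0.725 with an estimated correlation) and eosinophil and mast cell genes (14 tested, median -1.23, camera adjusted p = 0.0105, adjusted p = 0.725 with an estimated correlation) had medians of -2.52 and -2.18 over Che-1 silencing replicates 1 and 2, against 0.47 and 0.12 in replicate 3. Against control replicates 2 and 3 alone replicate 3 lay at 0.08 and -0.32, and control replicate 1 lay below the other control libraries by 1.16 and 1.20. The eosinophil and mast cell call ended without Che-1 silencing replicate 1 (camera adjusted p = 0.0645), with a minimum mean of 50 (camera adjusted p = 0.112) and with both pairs of like libraries summed (camera adjusted p = 0.0959). On the spike-in scale 1 neutrophil gene rose, and 2 eosinophil and mast cell genes rose and 2 fell. Adjusted over the list alone 0 neutrophil genes and 1 eosinophil and mast cell gene were lower on the relative scale. Il5ra, an eosinophil cytokine receptor, fell by 1.72 log2 units on the spike-in scale (SE 0.53), a call that ended without control replicate 1 (limma adjusted p = 0.0648) and without Che-1 silencing replicate 1 or 2 (limma adjusted p = 0.302 and 0.11). Mcpt8, a basophil protease, rose by 2.29 log2 units (SE 0.74), a call that ended without Che-1 silencing replicate 2 (limma adjusted p = 0.115). Prg3, an eosinophil granule protein, rose by 1.27 (SE 0.56), a call that ended with control replicate 1, 2 or 3 left out (limma adjusted p = 0.115, 0.113 and 0.109) and with Che-1 silencing replicate 2 or 3 left out (limma adjusted p = 0.0791 and 0.195). Mmp9, a neutrophil protease, did not pass (0.18, SE 0.53). Of 16 stem and progenitor genes 4 rose, and the list lay at a median of -1.29 and a mean of -0.73, with medians of -1.65 over Che-1 silencing replicates 1 and 2 and -0.48 in replicate 3 (camera adjusted p = 0.0215, adjusted p = 0.725 with an estimated correlation). Kit, the stem cell factor receptor, did not pass (0.21, SE 0.56), and Slamf1, a lymphocyte activation receptor, rose by 3.02 (SE 0.57).

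Dendritic cell (12 genes, median -0.87), megakaryocyte (17, -0.84), T and NK cell (24, -0.36) and stromal (14, -0.46) lists did not pass on the relative scale (camera adjusted p = 0.0713, 0.0713, 0.095 and 0.103), with 4, 1, 12 and 6 rises and 1, 0, 0 and 0 falls on the spike-in scale. All of them passed as lower without Che-1 silencing replicate 3 (camera adjusted p = 0.0090, 6.6e-06, 0.0047 and 0.0228), and the dendritic and stromal lists also without control replicate 1 (camera adjusted p = 0.0466 and 0.0306). The dendritic, megakaryocyte and stromal lists passed as lower with camera on the spike-in scale (camera adjusted p = 0.0027, 0.0075 and 0.0086). Without a length trend the dendritic, megakaryocyte and T and NK cell lists passed as lower (camera adjusted p = 0.0334, 0.0277 and 0.0268). Their medians over Che-1 silencing replicates 1 and 2 were -1.15, -1.76, -0.59 and -1.33 in the order first given, against -0.06, 0.80, 0.18 and -0.04 in replicate 3, or -0.17, 0.94, 0.09 and -0.16 against control replicates 2 and 3 alone. Cd209a, a lectin of dendritic cells, fell from 119 ± 9.44 to 30.1 ± 20.2 normalized counts (SD, n = 3 each), while Irf8, a transcription factor of dendritic and B cells, rose by 2.62 log2 units (SE 0.58). Gzmb, a protease of killer lymphocytes, rose by 3.64 log2 units (SE 0.56), and the T cell genes Cd8a (0.04, SE 0.56) and Cd8b1 (-0.49, SE 0.54) did not pass. Plek, a platelet protein, rose by 2.23 log2 units (SE 0.58), and Vwf, von Willebrand factor, did not pass (0.51, SE 0.58). Cxcl12, a chemokine of marrow stroma, did not pass (-0.70, SE 0.59), whereas the collagens Col1a1 and Col3a1 rose by 1.83 (SE 0.57) and 1.53 (SE 0.58), calls that ended without control replicate 2 (limma adjusted p = 0.0547 and 0.0983) or 3 (limma adjusted p = 0.0516 and 0.0912).

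Among the authors' deposited values, 8 genes were higher and 5 lower at an adjusted p of at most 0.05, among 16825 genes with a p-value. The authors' deposited table listed Glycam1 at a fold of 48.9, Krt17 at 36.5, Il10, an anti-inflammatory cytokine, at 33.7, Ccl12 at 27.9, Avil at 23.6, Ido1, an enzyme of tryptophan breakdown, at 19.8 and Lipg, a lipase, at 17.8. The other genes past that threshold in the authors' deposited table were Xist, higher, and Ddx3y, Eif2s3y, Kdm5d, Uty and 4933409K07Rik, each with a mean of 0 in the libraries labelled Che-1 silencing. The authors' deposited table gave Aatf a fold of 4.10 with an adjusted p = 0.186. Its median fold over all genes was 2.95, and 90.1% of the 16825 genes had a higher mean in the libraries labelled Che-1 silencing. Of the genes past the authors' threshold 11 were in the limma fit, and all 11 passed there on the spike-in scale. Across 14594 genes, which are not independent replicates, the authors' log2 folds and those computed here had a Pearson correlation of 0.965.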

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

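The swap test was chosen only after the values were seen, and the test on sex was fixed before its 3 genes were looked at.

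Xist, the RNA that coats the inactive X chromosome in females, gave a signal in data outside the fits. The authors' deposited table lists it at a mean of 68685 normalized counts in the libraries labelled Che-1 silencing and 5.64 in the control libraries. In the other direction, Ddx3y, Eif2s3y, Kdm5d and Uty had 5716, 9151 and 10310 reads together in control replicates 1, 2 and 3 and 0 in each library labelled Che-1 silencing. A swap of libraries between the groups cannot be told apart: 0 libraries held Y-linked reads against their group, but an exchange of both whole groups would give the same 0, and Aatf goes against its label. Female mice behind the libraries labelled Che-1 silencing and male mice behind the control libraries are a candidate explanation: Kdm5c, Eif2s3x and Ddx3x, X-linked genes that escape inactivation, lay a median of 0.47 log2 units above the other X-linked genes on the relative scale. Sex is then confounded with the label in all 6 libraries, and no comparison above separates them.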

How the results depend on the processing

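Sums of libraries, limma without moderation and the length trend were chosen only after the data were seen. The shift of the median gene kept its direction under every alternative run, at 1.20 to 1.86, as did the spike-in totals, at -1.70 to -0.97, and Aatf was higher under every alternative run. Leaving out each library in turn gave 3223 to 11012 rises and 25 to 234 falls on the spike-in scale, 0 to 4046 rises and 4 to 3666 falls on the relative scale, 4 to 9 lower lists, and 1.55 to 2.37 for Aatf on the spike-in scale. Fewer libraries enter those fits, and the largest relative counts came without Che-1 silencing replicate 3. Control libraries 2 and 3 summed gave 3451 rises, 55 falls and Aatf at 1.79 (limma adjusted p = 0.0567), and both pairs of like libraries summed gave 528, 28 and 1.56 (limma adjusted p = 0.158). Over all alternatives Aatf's adjusted p ranged from 2.2e-136 to 0.158 on the spike-in scale and from 0.0082 to 0.671 on the relative scale. Without moderation 0 genes rose and 4 fell on the spike-in scale, with Aatf at 1.98 (adjusted p = 0.0746), and 13 rose and 11 fell on the relative scale. Falls on the spike-in scale numbered 52 with a minimum mean of 50 (fewer genes tested), 53 by DESeq2 and 1560 with library weights, whose estimation stopped before convergence. Relative rises and falls numbered 4671 and 4477 with library weights, with Aatf at 0.58 (limma adjusted p = 0.0082), 2189 and 1777 by DESeq2, 1590 and 1483 at an adjusted p of 0.1, 11 and 12 without a filter, 2 and 7 on the upper quartile scale, 12 and 8 on the quantile scale, 1 and 7 without a trend, and 1 rise with a pseudocount of 0.1. The cause was not tested. With an estimated correlation 0 lists were higher and 0 lower. Lower lists numbered 8 with camera on the spike-in scale and 8 without a length trend. With both pairs summed the DNA damage and eosinophil lists lost their calls (camera adjusted p = 0.162 and 0.0959), and with the replicate block the plasma cell list did (0.0501). Among 452 values of named genes 175 had passed, and 173 lost the call under at least 1 alternative. On the spike-in scale limma without moderation ended 173 calls, both pairs of like libraries summed ended 125, and any other alternative at most 12. With library weights 9 genes not past the threshold were lower on the spike-in scale and passed: Zbtb46 -0.24, Vwf -0.54, Gp1ba -0.62, Pf4 -0.20, Clec1b -0.19, Mmp9 -0.83, Kit -0.21, Lepr -0.23 and Cd8a -0.23.

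Replicate numbers did not pair the libraries: same-numbered deviations correlated at 0.17, -0.15 and 0.18, and not every library correlated best with its own number. With the replicate number as a block 6719 genes rose and 83 fell on the spike-in scale and 0 and 5 on the relative scale. The death pathway and interferon lists passed as higher there (camera adjusted p = 0.0498 and 0.0426), and the dendritic and megakaryocyte lists as lower (0.0329 each). Depth limits genes near the minimum, where 1 read is a large share.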

Other observations

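The tests on summary rows, on a few dominant genes, on spike-in amounts and on replicate 3 as RNA of the control mice were chosen only after the values were seen; those on genetic background and germinal centre genes were fixed before their result, although a few genes off in Che-1 silencing replicates 1 and 2 had been noticed.

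Several immune genes were far higher on the spike-in scale in all 3 libraries labelled Che-1 silencing. They were chosen after their values were seen. Of these, Il10, Cxcl9, Cfb, Slpi and Ido1 did not pass on the relative scale (limma adjusted p = 0.0723 to 0.0741). Il10, an anti-inflammatory cytokine, had 16.0 ± 5.92 normalized counts in the control libraries and 540 ± 269 in the libraries labelled Che-1 silencing (SD, n = 3 each). Cxcl9, a chemokine induced by interferon gamma, had 448 ± 110 and 6604 ± 3095. Cfb, a complement protease, had 972 ± 115 and 15306 ± 8526, and Slpi, a protease inhibitor, had 577 ± 112 and 11660 ± 5679. Ido1 had 4.48 ± 0.877 and 88.8 ± 21.1, with its highest value, 113, in replicate 3. Lef1, a transcription factor of early lymphocytes, had 503 ± 227 and 225 ± 61.2, a difference that passed on neither scale (limma adjusted p = 0.0569 on the spike-in scale and 0.0559 on the relative scale). Shorter transcripts lay above longer ones: the median relative log2 difference was 0.22 among the 3622 genes with the shortest transcripts and -0.17 among the 3621 with the longest.

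The level of most genes per spike-in was higher in the libraries labelled Che-1 silencing. Summary rows in the authors' size factors are argued against, since factors from spike-ins alone left a median difference of 1.53 log2 units. A few genes did not take most of the counts: the 10 most abundant held 9.40% of the summed deposited means in the control group and 6.48% in the other. That share cannot decide the shift, since abundant genes take reads from spike-ins and other genes alike. Uneven amounts of spike-in between libraries cannot be told apart from a change in RNA: Che-1 silencing replicates 1 and 2, alike in profile, differed by 0.73 log2 units in their median level, less than the 1.54 between groups, while single spike-ins put the group difference in reads anywhere from -1.87 to -0.40. A change tied to the label stays open and untested, since Aatf was not lower.

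Che-1 silencing replicates 1 and 2 stood apart from replicate 3. Across genes, which are not independent replicates, replicate 3 had a Spearman correlation of 0.974 with control replicate 2 and 0.925 with Che-1 silencing replicate 1. That replicate 3 was made from the mice behind the control libraries is argued against by 0 reads of the 4 Y-linked genes in it, while a control mouse of the other sex stays open. Another genetic background of replicates 1 and 2 cannot be told apart: 2 genes, Trim12a and Gjc3, had at most 3 reads in both and at least 100 normalized counts in each of the other libraries, against at most 1 such gene in any other pair and 3 in replicate 3 alone, and at least 10 had been set in advance. More germinal centre B cells in replicates 1 and 2 may explain part of the difference. The test used 14 germinal centre genes whose values had not been seen, though the names of Klhl6 and Swap70 had. They lay a median of 1.07 log2 units higher in replicates 1 and 2 than in replicate 3, just past the bound of 1 set in advance. Of them 14 of 14 lay above 0 and 7 above 1. The test did not compare them with other genes. The mitosis and replication lists also separated these libraries, at 1.44 and 1.23 above the control mean over replicates 1 and 2 and 0.17 and 0.01 in replicate 3. The result therefore does not single out germinal centre cells.

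The most abundant of those 14 genes were Klhl6 (32174 and 54512 normalized counts in replicates 1 and 2, 3350 in replicate 3), Gna13 (29383, 45821 and 5145) and Swap70 (30048, 51881 and 11886). All 14 had at least 10 normalized counts in every control library, and 2 of them stand in other lists.

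Among all 10 splits of the 6 libraries into groups of 3, 1, the real split, gave as many calls on the spike-in scale (9854 genes, against 672 in the highest other split). On the relative scale 2 splits gave at least the 4 real calls, and the split with control replicate 1 and Che-1 silencing replicates 1 and 2 on the same side gave 352, which points to a structure of the libraries across the labels. With 10 splits the share cannot fall under 0.1, so the splits are too few for a test at 0.05.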
